A study of Mus musculus with 8 samples.

How the data were processed

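RNA sequencing was carried out on olaparib-resistant ID8 cells, a mouse ovarian cancer line, after 72 hours with DMSO (the solvent control), olaparib, EZM8266 or both compounds. The 8 libraries form 4 groups of 2. The groups and replicate numbers were taken from the sample titles. The treatment label of combination replicate 2 reads EZM8267 in place of EZM8266, and the library was kept in the group its title gives. Per the labels' protocols, total RNA was depleted of ribosomal RNA, and libraries were made with the KAPA mRNA HyperPrep kit, amplified, and read as pairs of 150 bases on a NovaSeq X. The labels call the replicates treatment or transfection replicates and do not state whether they are separate cultures, so p-values measure the spread between these libraries, which may be technical.

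The deposited table holds whole-number counts of fragments per gene, not normalized. Per the submitters' processing notes, FastQC 0.11.8, MultiQC 1.7, HISAT2 2.1.0, Subread 1.6.2 and the mouse build mm10 were used. Per the file headers, featureCounts counted read pairs over the exons of GENCODE M18 genes, let 1 fragment count for every gene it overlapped, and was run with strand setting 1, which counts fragments whose first read lies on the strand of the gene. The kit is one that marks the strand with dUTP, so that the first read lies on the strand opposite to the transcript. The table has 54146 rows. Gene symbols and gene positions on the opposite strand came from the GENCODE M21 annotation of the same assembly, which named 54079 rows and left 67 unnamed, and the length of the merged exons was equal, to the base, for all 54146 rows. All per-sample columns were used.

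Each row was placed in 1 of 4 classes by what is annotated on the other strand. A row with at least 50 bases of its exons over an exon of an opposite-strand gene was put in the exon class, and the next classes were rows inside the body of such a gene only, rows within 5000 bases downstream of such a gene, and rows with none of these. Rows are named below by the opposite-strand gene whose exon they overlap, with the symbol of the row in parentheses. The strand leakage of a library was taken as the count of the Rmrp row as a percent of the Rmrp and Ccdc107 rows together. Exons of Ccdc107 overlap the Rmrp gene on the other strand by 124 bases. The Ccdc107 row counts only Rmrp fragments that reach its exons, so the share is a relative measure. Shares of fragments assigned have Wilson 95% confidence intervals. The floor of a library is 3 counts, expressed as CPM, counts relative to the library total. Intervals and floors cover counting error only.

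Differential tests used edgeR 4.0.16 in R 4.3.3 with its quasi-likelihood F test on the counts as deposited, TMM scaling and filterByExpr with a minimum count of 10 and a minimum total of 15. All 8 libraries entered 1 fit with 4 group means and no covariate. The filter kept 6379 rows, of which 3555 were in the exon class, 703 in the gene body class, 1002 in the downstream class and 1119 in the class with no annotation. The 6 comparisons were olaparib, EZM8266 and the combination each against DMSO, the combination against olaparib and against EZM8266, and the interaction of both compounds. A row was called at a Benjamini-Hochberg adjusted p under 0.05. Group means are TMM-scaled CPM with the SD. Exceptions, relative to the unscaled total, are the 4 drug target genes, the Gm10800 and receptor rows and the means of 4 libraries. Log2 fold changes have the standard error (SE) of the fit.

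The rule for named genes, the 30 gene lists, the tests and most of the other settings tried were fixed before the data were examined. The rule takes Ehmt1, Ehmt2, Parp1 and Parp2, up to 8 called genes of each direction per treatment against DMSO and up to 5 in the other comparisons, with a mean of at least 5 CPM, no overlap between the groups and a symbol that is not a Gm number, a Rik name or a bare identifier, plus up to 4 members of each list described. Read by the symbol of the row, the rule takes 5 rows for EZM8266 against DMSO, 4 for the combination against DMSO and 2 for the combination against olaparib. Read by the opposite-strand gene it takes 9, 9 and 5. That second reading, and the remaining called rows that are named, were chosen after the values were seen.

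Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, for lists with at least 5 tested rows, two-sided, with Benjamini-Hochberg adjustment over the lists within a comparison. The test was repeated with an estimated correlation. Each list was tested on the rows of its members, as planned, and, as an addition made after the strand of the counts was seen, on the rows whose exons overlap an exon of a member on the opposite strand.

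The other settings fixed in this way were DESeq2 1.42.0, RLE scaling, no filter on low counts, a filter of at least 1 CPM in at least 4 libraries, a replicate block, a fit of only the 2 groups compared, an estimated correlation for the lists, and each library left out in turn. The filter of 1 CPM was meant as a stricter one but kept 14446 rows, more than the main filter. Leaving out a library leaves its group with 1 sample, which is then assumed to vary like the other groups. It also loosens the main filter, so these fits tested 7133 to 7660 rows and a list could hold more rows. A call or list lost in such a fit may therefore reflect the changed rows and not that library's values. Settings added after seeing the data were the omission of DMSO replicate 1 with olaparib replicate 2, exon-class rows only, counts summed per opposite-strand gene, the leakage share as a covariate, removal of the 6 most abundant rows, and a replicate block with crossed DMSO numbers. Comparisons of 4 libraries with 4, averaging each compound over the other, and the values of named rows in the fit of only the 2 groups compared were also added after seeing the data. Replicates of a group were compared by a chi-square of their counts over the tested rows, which gave 7.10 to 21.5 per degree of freedom, so no library was treated as a duplicate.

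The scripts were tested on simulated data drawn from the means and library sizes of these samples, with 200 changed rows and 6087 rows in the fit. Rows changed 4-fold were called in 73.0% of cases for olaparib against DMSO, 77.8% for EZM8266 against DMSO and 75.8% for the combination against DMSO. At 2-fold the shares were 32.3%, 33.8% and 15.2%, and at 1.5-fold they were 11.1%, 7.20% and 3.10%. False calls made up 5 of 79, 3 of 80 and 5 of 64 calls. A list shifted in the simulation of EZM8266 against DMSO had a camera p of 8.21e-16, and 0.000918 with an estimated correlation, and an unshifted list had 0.234. Simulated rows were drawn independently of each other, whereas the histone list had an estimated correlation of 0.619 in the data for EZM8266 against DMSO. The simulation therefore does not test camera or the false calls where rows are correlated. Figures were drawn with matplotlib 3.10.9, and the annotation steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.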

Results

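Messenger RNA and other ribosome-depleted RNA was measured in ID8-OR cells, a form of the mouse ovarian cancer line ID8 that is resistant to olaparib. Olaparib inhibits the PARP enzymes, which attach ADP-ribose to proteins at DNA breaks. EZM8266 is described in the labels as an inhibitor of EHMT1 and EHMT2, the histone methyltransferases that place repressive methylation on lysine 9 of histone H3. Cells were kept for 72 hours with DMSO, olaparib, EZM8266 or the combination, with 2 libraries in each of the 4 groups. The libraries held 19743299 to 30329847 fragments, of which 4.54% (EZM8266 replicate 2, Wilson 95% interval 4.53 to 4.55%) to 5.4% (olaparib replicate 1, 5.39 to 5.41%) were assigned to genes. The counts summed to 973382 to 1680974 per library, over 15882 to 19399 rows with at least 1 count, and the floor of 3 counts lay between 1.78 and 3.08 CPM.

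The counts fell mainly on the strand opposite to the expressed genes. Rows whose exons overlap an exon of another gene on the opposite strand made up 15.2% of the table and held 83.8% to 88.6% of the counts of a library, and 89 of the 100 most abundant rows were of this kind. The row of Ccdc107, whose exons overlap the gene of the abundant noncoding RNA Rmrp on the other strand, held 85234 to 194016 counts. The row of Rmrp itself held 899 to 3314. The row of the abundant nuclear RNA Malat1 held 46 to 176 counts, and a row within it on the other strand held 6513 to 11585. The rows of Gapdh, a glycolytic enzyme, and Actb, the cytoskeletal actin, held 15 to 40 and 201 to 750 counts. A row that overlaps an exon of a gene on the other strand is therefore described below as fragments on the strand of that gene. Its counts cover all exons of the row, and where in the row they lie was not measured. The overlap made up 74% of the row's exons for Thbs1 (Gm29233 row), 15.5% for Serpinb9b, 14.2% for Trdc, 4.2% for F13a1 and 3.4% for Cxcl10. A value of such a row may therefore come from outside the overlap. Such a value leaves out the rest of the gene, and the partners of an overlapping pair cannot be fully separated.

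The libraries also differed in ways the groups do not follow. Of the tested rows, 13 held at least 2 times as many counts in both DMSO replicate 1 and olaparib replicate 2 as in any other library, most of them predicted genes such as Gm10800 and Gm21738 known to lie over satellite repeats. The Gm10800 row held 23746 counts (22502 CPM) in DMSO replicate 1 and 22517 counts (18644 CPM) in olaparib replicate 2, against 1182 to 4277 counts in the other libraries. The share of the Rmrp row in the Rmrp and Ccdc107 rows, a measure of strand leakage, was 1.24% and 1.68% in the DMSO libraries, 1.53% and 1.42% with olaparib, 1.55% and 1.04% with EZM8266, and 1.44% and 1.21% with the combination. Sample numbers in the labels run from 33 to 36 in the libraries with EZM8266 and from 41 to 44 in those without it, so each block of numbers holds libraries of 1 kind only with respect to EZM8266, and an effect of such a block cannot be told apart from that of EZM8266.

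**Figure D1:**
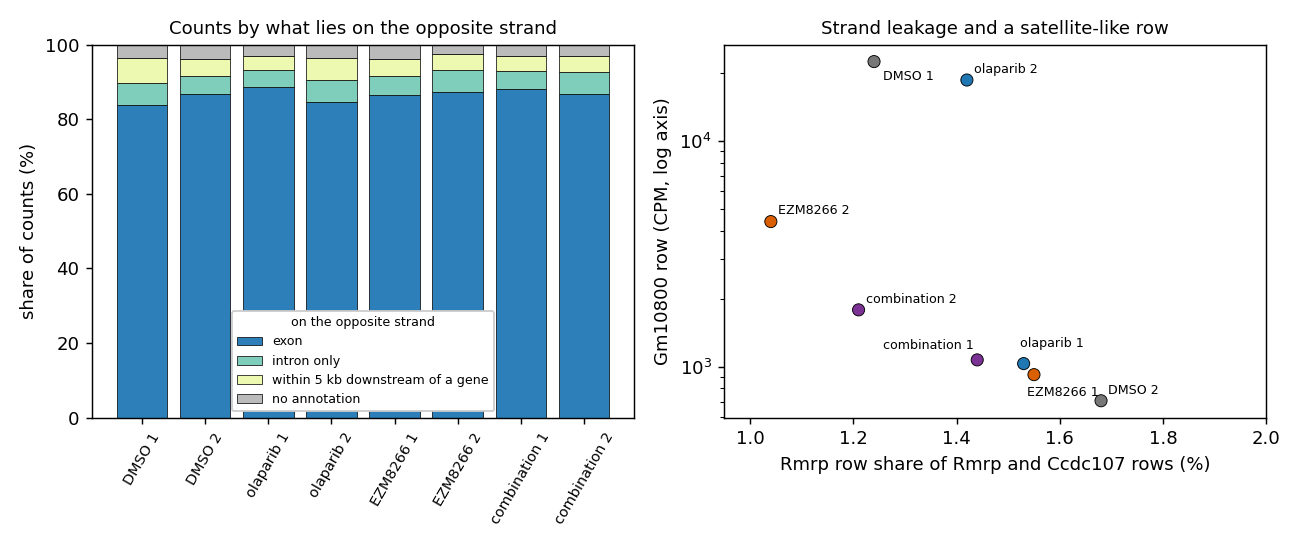
The left panel plots the share of counts (%) in each library by what is annotated on the opposite strand of a row, and the right panel plots the Gm10800 row (CPM, log axis) against the share of the Rmrp row in the Rmrp and Ccdc107 rows (%), with 1 point per library. Rows opposite an exon hold 83.8% to 88.6% of the counts, and DMSO replicate 1 and olaparib replicate 2 stand apart in Gm10800.

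The genes of the drug targets were covered thinly. The Parp1 row (chromosome 1, 180568924 to 180601254, mm10) held 8 to 61 counts, with 28.6 ± 10.9 CPM in DMSO, 21.9 ± 0.52 with olaparib, 17.2 ± 12.8 with EZM8266 and 16.8 ± 0.55 with the combination (SD, n = 2). The Ehmt2 row (chromosome 17, 34898469 to 34914052) held 7 to 30 counts, with 16.5 ± 1.90 CPM in DMSO, 11.5 ± 1.35 with olaparib, 6.69 ± 0.71 with EZM8266 and 12.8 ± 4.99 with the combination. Ehmt1 (chromosome 2, 24789928 to 24919614) and Parp2 (chromosome 14, 50807841 to 50821301) had 1 to 10 and 1 to 9 counts per library and did not pass the filter. The Parp1 and Ehmt2 rows have no annotated gene on the other strand, and neither was called in any of the 6 comparisons. The Ehmt2 row had a log2 fold change of -1.40 ± 0.48 (SE) with EZM8266 against DMSO, with an edgeR adjusted p of 0.739. These compounds act on the enzymes, and the rows measure fragments on the strand opposite to the transcripts, so they do not test target inhibition.

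Olaparib against DMSO asked what the PARP inhibitor does alone in resistant cells. None of the 6379 tested rows passed the threshold with edgeR (smallest adjusted p 0.999) or with DESeq2, and 117 rows had an unadjusted p under 0.05 where chance gives 319. Without olaparib replicate 1 the count was 1, the row of mt-Tq, a mitochondrial transfer RNA (adjusted p 0.00058), with 1147 counts in olaparib replicate 2 and 187 to 398 in the other libraries. In log2 CPM across the tested rows, DMSO replicate 1 correlated more with olaparib replicate 2 (0.967) and DMSO replicate 2 with olaparib replicate 1 (0.974) than with each other (0.957), and an exchange of labels between these groups, which would hide a difference, was not excluded. On the strand of Rnf213, a large ubiquitin ligase, levels were 633 ± 15.3 CPM in DMSO and 765 ± 84.2 with olaparib (SD, n = 2), and on the strand of Cxcl10, an interferon-induced chemokine, they were 45.3 ± 10.1 and 68.1 ± 6.65 CPM. Among the fixed lists, the type I interferon response list, read through the opposite strand, was higher with olaparib, with all 5 of its rows above 0, a median log2 fold change of 0.29 and a camera adjusted p of 0.00091. With an estimated correlation the list had an adjusted p of 0.248, and 0 of its 5 rows passed when adjusted over the list alone or over all rows. The list was not past the threshold without DMSO replicate 2 (adjusted p = 0.153) or with a low-count filter of 1 CPM in 4 libraries, which kept 14446 rows (0.104). The median SE of a log2 fold change was 0.38, and 0.15 over the 1329 rows with a mean of at least 100 counts, so a small change in a thinly covered gene was not detectable at this depth.

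EZM8266 against DMSO asked what inhibition of EHMT1 and EHMT2 does alone. Fragments on the strand of Serpinb9b, a serine protease inhibitor (Gm36099 row, chromosome 13, 33031202 to 33034560), rose from 101 ± 13.2 to 401 ± 55.9 CPM (SD, n = 2), a log2 fold change of 1.99 ± 0.16 (SE, edgeR adjusted p 7.44e-05). Fragments on the strand of F13a1, the A subunit of coagulation factor XIII (Gm30489 row, chromosome 13, 36963239 to 36973329), rose from 65.4 ± 5.28 to 185 ± 16.2 CPM (log2 fold change 1.49 ± 0.16, adjusted p 0.000637). Counts in the row of Gdnf, which encodes a secreted neurotrophic factor (chromosome 15, 7810846 to 7837575), rose from 180 ± 14.7 to 383 ± 32.3 CPM (log2 fold change 1.09 ± 0.13, adjusted p 0.00208). Fragments on the strand of Thbs1, the matrix glycoprotein thrombospondin 1 (Gm29233 row, chromosome 2, 118123451 to 118124047), went from 726 ± 24.8 to 351 ± 66.8 CPM and fell by 1.05 ± 0.14 on the log2 scale (adjusted p 0.00487).

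In all, 13 rows passed with EZM8266, 12 higher and 1 lower, and 11 of them overlap an opposite-strand exon. The balance was less one-sided in settings that called more rows, with 14 higher and 10 lower without EZM8266 replicate 1, 27 and 15 with no filter on low counts, and, in settings added after seeing the data, 30 and 16 with the leakage share as a covariate and 53 and 31 with a replicate block of crossed DMSO numbers. Further rises were on the strands of Entpd4b, a nucleotide-hydrolysing enzyme of the Golgi (Gm27177 row, log2 fold change 3.23 ± 0.33), Trdc, the constant region of the T cell receptor delta chain (Gm43434 row, 2.86 ± 0.38), Ica1l (Fam117b row, 2.55 ± 0.41) and Abcb1a, a drug efflux pump (Gm42686 row, 1.53 ± 0.27). Smaller rises were seen for Tmem140 (Cyren row, 0.90 ± 0.15), Smpd3, a sphingomyelinase (Prmt7 row, 0.87 ± 0.15), and the noncoding Gm20186 (Gm26809 row, 0.77 ± 0.13). The Pax8 row, which overlaps an exon of the noncoding Gm13415, rose from 3.01 ± 0.11 to 37.7 ± 12.7 CPM (log2 fold change 3.58 ± 0.52), and the Gm49314 row, with no annotated partner, from 2.70 ± 0.33 to 22.8 ± 0.13 CPM. The Gm27177 row overlaps exons of 2 opposite-strand genes, Entpd4b and Loxl2, so its counts cannot be assigned to Entpd4b alone. The Gdnf row has no annotated gene on the other strand, so its counts can be leakage of Gdnf transcripts or an unannotated RNA. It held 173 to 476 counts, against 15 to 40 in the Gapdh row and 201 to 750 in the Actb row. The rows of Gapdh and Actb differ widely, so they do not tell how much of the Gdnf row leakage could make up. The level of Gdnf transcripts was not measured, so the Gdnf row is not a measure of that gene. DESeq2 called 15 rows, and 365 rows had an unadjusted p under 0.05. The count was 6 without DMSO replicate 1, 5 without DMSO replicate 2, 8 without olaparib replicate 1, 24 without EZM8266 replicate 1 and 7 without EZM8266 replicate 2. Without DMSO replicate 1 and olaparib replicate 2 together, the libraries rich in Gm10800, it was 3. Serpinb9b, F13a1, Gdnf, Thbs1 and Entpd4b passed with any 1 library left out. With only the DMSO and EZM8266 libraries in the fit the count was also 3, Serpinb9b (adjusted p 0.0124), F13a1 (0.0461) and Entpd4b (0.0461), while Gdnf (0.0874) and Thbs1 (0.113) were not called. Trdc failed without DMSO replicate 2 (0.121), and Pax8 without DMSO replicate 1 (0.0884), DMSO replicate 2 (0.15) or EZM8266 replicate 2 (0.089). Abcb1a failed without any 1 of the 8 libraries (0.0618 to 0.464), with the replicate block (0.0797) and with DESeq2 (0.119), and Smpd3 without any 1 library (0.0562 to 0.495). Tmem140 and Gm20186 failed with the replicate block (0.0637 and 0.0635) and without 6 of the libraries each, and the others without at least 3.

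**Figure D2:**
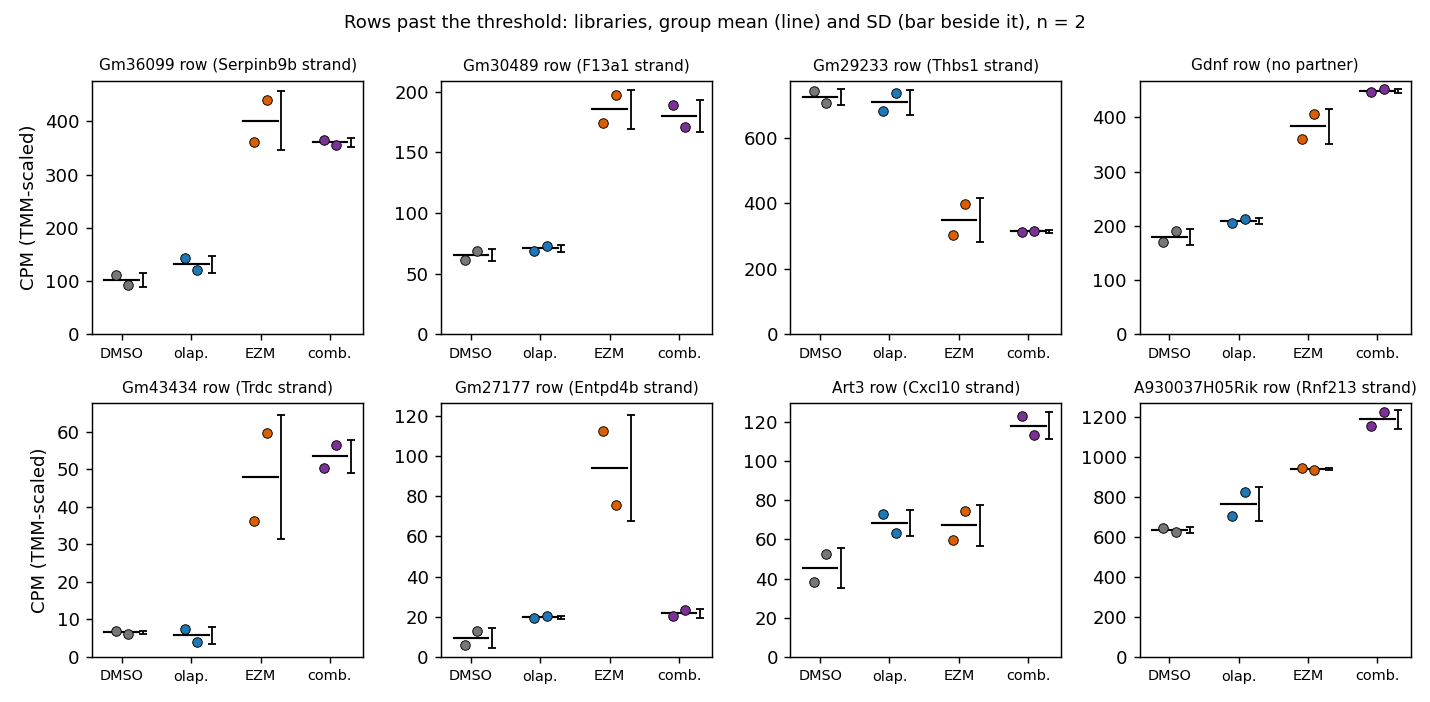
Each panel plots TMM-scaled CPM of 1 called row in the 8 libraries by group, with the group mean as a line and the SD (n = 2) as a bar beside it. Serpinb9b, F13a1, Gdnf and Trdc are higher and Thbs1 is lower in both groups with EZM8266, and Cxcl10 and Rnf213 are highest with the combination.

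The combination against DMSO asked what both inhibitors do together. Serpinb9b fragments rose to 360 ± 7.67 CPM (log2 fold change 1.84 ± 0.16, edgeR adjusted p 0.000199), and those on the strand of F13a1 to 180 ± 13.3 CPM (1.45 ± 0.16, adjusted p 0.000947). The Gdnf row rose to 449 ± 3.58 CPM (1.32 ± 0.13, adjusted p 0.000485). On the strand of Thbs1 the level went to 314 ± 3.20 CPM and fell by 1.21 ± 0.14 on the log2 scale (adjusted p 0.0015). Fragments on the strand of Cxcl10 (Art3 row, chromosome 5, 92331827 to 92414628) rose from 45.3 ± 10.1 to 118 ± 6.95 CPM (1.36 ± 0.21, adjusted p 0.016), and on the strand of Rnf213 (A930037H05Rik row, chromosome 11, 119448788 to 119491298) from 633 ± 15.3 to 1190 ± 48.1 CPM (0.91 ± 0.12, adjusted p 0.00338).

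The combination moved 14 rows past the threshold, 12 higher and 2 lower, against 29 higher and 16 lower with no filter on low counts. The others were on the strands of Trdc (log2 fold change 3.03 ± 0.38), Abcb1a (1.63 ± 0.27), Tmem140 (0.94 ± 0.16), Gm20186 (0.77 ± 0.13) and Sp140, a nuclear body protein (Gm17017 row, 1.61 ± 0.29), together with Gm49314 (3.05 ± 0.52) and Gm10552, a row inside the body of Sp140 (2.04 ± 0.30). The row of Thbs1 itself, which shares 208 bases with Gm29233, fell by 1.76 ± 0.31 on the log2 scale. DESeq2 called 16 rows, and 312 rows had an unadjusted p under 0.05. The count was 6 without DMSO replicate 1, 6 without DMSO replicate 2, 6 without combination replicate 1 and 9 without combination replicate 2, and 5 without DMSO replicate 1 and olaparib replicate 2 together. Serpinb9b, F13a1, Gdnf and the Gm29233 row on the strand of Thbs1 passed with any 1 library left out. Cxcl10 failed without DMSO replicate 1 (adjusted p 0.184), combination replicate 1 (0.17) or combination replicate 2 (0.0649), Rnf213 without DMSO replicate 2 (0.0567) or combination replicate 2 (0.0649), Trdc without DMSO replicate 2 (0.0567), and each other row without at least 1 library.

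Genes of the type I interferon response, which cells switch on upon viral infection or sensing of nucleic acids, were higher together with the combination when read through the opposite strand. All 5 measured rows were above 0, with a camera adjusted p of 4.49e-09 against DMSO, and 4 of the 5 passed when adjusted over the list alone, while 0 passed over all rows. With an estimated correlation the adjusted p was 0.0504. Usp18, a protease that removes ISG15 (Gm44148 row), had 3.27 ± 3.24 CPM in DMSO and 24.8 ± 3.38 with the combination (log2 fold change 2.72 ± 0.59, SE), from 1 to 27 counts per library. Ifi35 (Gm11626 row) had 0.68 ± 0.22, Parp9, a PARP family member (Dtx3l row), 0.88 ± 0.27, its partner ubiquitin ligase Dtx3l (Parp9 row) 0.81 ± 0.25, and Eif2ak2, the kinase activated by double-stranded RNA (Gm26637 row, which overlaps exons of 2 opposite-strand genes), 0.31 ± 0.16. Parp9 and Dtx3l lie head to head and overlap by 458 bases, so these rows are not separate evidence. With EZM8266 against DMSO the list was also higher (adjusted p 0.0256, and adjusted p = 0.505 with an estimated correlation), with 0 of 5 rows past the threshold adjusted over the list alone. That call ended without DMSO replicate 2 (0.184), EZM8266 replicate 1 (0.167) or EZM8266 replicate 2 (0.0773), or with the filter of 1 CPM (0.0686). On the rows of the members themselves, which count fragments on the strand opposite to their transcripts, 9 were tested with the combination and 8 were above 0. The list had a camera adjusted p of 0.0665, and 0.919 with an estimated correlation. The Dtx3l and Parp9 rows belong to both readings, so the readings are not separate evidence. With the filter of 1 CPM 21 rows of members were tested, and the adjusted p was 9.4e-05. It was 0.0277 without combination replicate 2.

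**Figure D3:**
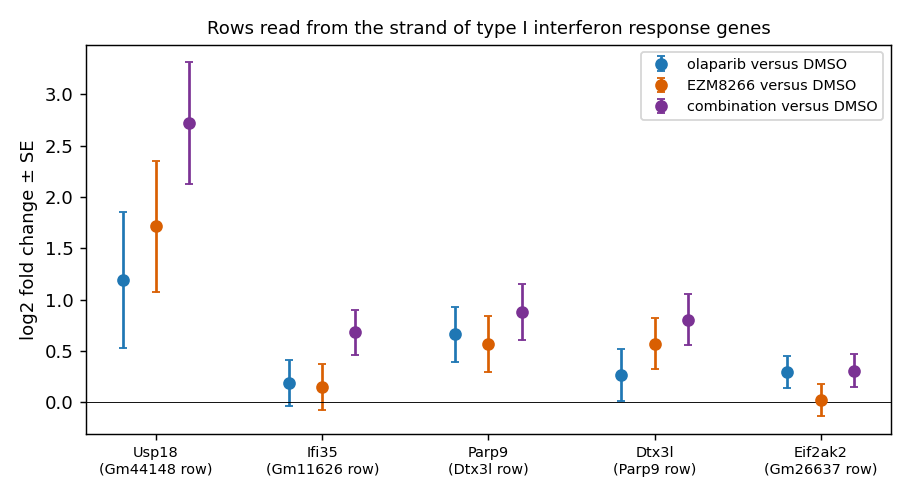
Log2 fold changes against DMSO with their SE are plotted for the 5 rows read from the strand of type I interferon response genes, with 1 colour per treatment. All points lie above 0, from 0.02 for Eif2ak2 with EZM8266 to 2.72 for Usp18 with the combination.

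Other lists moved with the combination against DMSO in the reading through the opposite strand. The chemokine and cytokine list was higher (5 of 5 rows above 0, camera adjusted p 0.0207, and 0.518 with an estimated correlation), and 1 row, Cxcl10, passed over all rows and adjusted over the list alone. The 5 rows lay on the strands of 4 genes. Beside Cxcl10 (log2 fold change 1.36 ± 0.21) the changes were small. They were 0.15 ± 0.14 for Cxcl16 (Zmynd15 row), 0.05 ± 0.13 for Tgfb3 (Gm48008 row) and 0.05 ± 0.26 for Il34 (Gm15895 row). The epithelial-mesenchymal and matrix list was lower (6 of 10 rows below 0, adjusted p 0.0207, and 0.518 with an estimated correlation). In it, Thbs1, the adhesive glycoprotein Fn1 (Apol7d row, log2 fold change -0.45 ± 0.12) and the matrix protein Tnc (8030451A03Rik row, -1.19 ± 0.38) passed adjusted over the list alone, 3 of 10 rows, and 1 passed over all rows. The chemokine list was not past the threshold without any 1 of the 8 libraries (adjusted p 0.0547 to 0.286), and the matrix list was not past it without any library other than DMSO replicate 2 (0.0547 to 0.609). Neither was past it with the filter of 1 CPM (0.0515 and 0.15). That filter instead moved the lists of nucleic acid sensing (0.0148) and MHC class I (0.0481) past the threshold, both higher. With 1 library left out the chemokine list held 6 or 7 rows in place of 5. Its losses, also without libraries outside the comparison, therefore do not show dependence on 1 library.

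On the rows of the members themselves, 2 lists were lower with EZM8266 against DMSO. These rows count fragments on the strand opposite to the members' transcripts. A lower list is therefore not a measure of lower expression of its genes. The replication-dependent histones, which package new DNA in S phase, had 21 of 24 rows below 0 (camera adjusted p 0.0129, and 0.771 with an estimated correlation), for example Hist1h4d at 58.5 ± 1.06 CPM in DMSO and 34.1 ± 15.9 with EZM8266. The epithelial-mesenchymal and matrix list had 11 of 14 rows below 0 (adjusted p 0.0197, and 0.771 with an estimated correlation). Adjusted over the list alone, 0 histone rows and 1 matrix row, Thbs1, passed, and 0 rows of either passed over all rows. With the combination the histones were lower as well (17 of 24 rows below 0, adjusted p 0.043, and 0.919 with an estimated correlation, with 0 rows past the threshold adjusted over the list alone). With olaparib alone 19 of 24 histone rows were below 0 and the list was not past the threshold (adjusted p 0.0648, and 0.903 with an estimated correlation). It passed, lower, with the replicate block (0.0152) and without DMSO replicate 1 (0.00831), olaparib replicate 1 (3.1e-05), EZM8266 replicate 1 (0.0216) or EZM8266 replicate 2 (0.0276). In the combination against olaparib the histones had an adjusted p of 0.919. With 1 library left out the matrix list held 15 to 18 rows in place of 14. DMSO replicate 2 had the highest strand leakage, 1.68%, and EZM8266 replicate 2 the lowest, 1.04%. Without DMSO replicate 2 the adjusted p was 0.735 for the histones and 0.556 for the matrix list with EZM8266, and 0.969 for the histones with the combination. Without EZM8266 replicate 2 these values were 0.85, 0.939 and 0.0531. The matrix list was also not past the threshold without combination replicate 1 (0.0872) or 2 (0.0792), nor the histones with the combination without olaparib replicate 1 (0.0918), olaparib replicate 2 (0.0876) or combination replicate 2 (0.936), or with the filter of 1 CPM (0.185).

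The combination against olaparib asked what EZM8266 adds in cells that already receive the PARP inhibitor. Serpinb9b fragments rose from 132 ± 15.8 CPM with olaparib to 360 ± 7.67 with both (SD, n = 2; log2 fold change 1.45 ± 0.15, edgeR adjusted p 0.00205). Those on the strand of F13a1 rose from 71.2 ± 2.85 to 180 ± 13.3 CPM (1.34 ± 0.15, adjusted p 0.00205), on the strand of Trdc from 5.71 ± 2.33 to 53.4 ± 4.36 CPM (3.19 ± 0.39), and in the Gdnf row from 209 ± 5.51 to 449 ± 3.58 CPM (1.10 ± 0.13). On the strand of Thbs1 the level went from 709 ± 38.7 to 314 ± 3.20 CPM and fell by 1.17 ± 0.14 on the log2 scale, and on the strand of Nrn1, a neuronal growth protein (Fars2 row, chromosome 13, 36117412 to 36726280), from 658 ± 63.8 to 398 ± 7.15 CPM, and fell by 0.73 ± 0.12. The 6 called rows were 4 higher and 2 lower, against 22 higher and 20 lower with no filter on low counts. DESeq2 called 8, and 243 rows had an unadjusted p under 0.05. The count was 11 without EZM8266 replicate 1 and 13 without EZM8266 replicate 2. Trdc failed without olaparib replicate 2 (adjusted p 0.0555). Nrn1, whose Fars2 row overlaps exons of 2 opposite-strand genes, failed with RLE scaling (0.051), with the replicate block (0.0872) and without any 1 library of the DMSO, olaparib and combination groups (0.0652 to 0.687).

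Of the lists read through the opposite strand, the interferon response was higher with the combination than with olaparib (5 of 5 rows above 0, camera adjusted p 0.00541), and the matrix list (6 of 10 below 0, 0.00981) and the list of the machinery of H3K9 methylation (8 of 10 below 0, 0.0353) were lower. With an estimated correlation the adjusted p was 0.363, 0.553 and 0.571. Adjusted over the list alone, 0 of 5 interferon rows, 3 of 10 matrix rows (Thbs1, Fn1 and Tnc) and 0 of 10 H3K9 rows passed. In the H3K9 list the smallest p values were for the methyltransferase Setdb1 (Gm37500 row, log2 fold change -0.82 ± 0.37) and its cofactor Atf7ip (Gm44140 row, -0.59 ± 0.30). The interferon call ended without olaparib replicate 2 (0.0661) or combination replicate 1 (0.256), the matrix call without DMSO replicate 1 (0.0602), olaparib replicate 2 (0.365) or combination replicate 1 (0.577), and the H3K9 call without DMSO replicate 1 (0.0602), olaparib replicate 1 (0.102), olaparib replicate 2 (0.18) or combination replicate 1 (0.782). With the filter of 1 CPM the matrix call (0.123) and the H3K9 call (0.107) ended too.

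The combination against EZM8266 asked what olaparib adds to the EHMT1 and EHMT2 inhibitor. With edgeR 0 rows passed, 98 had an unadjusted p under 0.05, and DESeq2 called 1. That row was Gm27177 on the strand of Entpd4b and Loxl2 (chromosome 14, 69582164 to 69683286). It stood at 94.2 ± 26.3 CPM with EZM8266 and 21.8 ± 2.30 with the combination. The log2 fold change was -2.12 ± 0.31 (edgeR adjusted p 0.0801, DESeq2 adjusted p 0.00562). The Cxcl10 strand was at 67.2 ± 10.5 CPM with EZM8266 and 118 ± 6.95 with the combination, and was not called. The interferon list read through the opposite strand was higher with the combination (5 of 5 rows above 0, camera adjusted p 0.00163), with 0 rows past the threshold adjusted over the list alone and an adjusted p of 0.279 with an estimated correlation. That call ended without EZM8266 replicate 1 (0.21) or combination replicate 1 (0.142). The edgeR count was 1, the Gm27177 row, without DMSO replicate 1 (0.0316), DMSO replicate 2 (0.0217) or EZM8266 replicate 2 (0.0179) and with the filter of 1 CPM (0.00334). It was 3 without combination replicate 2, the rows of Rn7s1, Gm47287 and Tuba1c, which held 51 to 55 counts in combination replicate 1 and at most 15 in any other library.

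The interaction of both compounds asked whether the effect of one depends on the other. With edgeR 0 rows passed (smallest adjusted p 0.196), 103 had an unadjusted p under 0.05, and DESeq2 called 1. It was again the Gm27177 row on the strand of Entpd4b and Loxl2 (log2 difference -3.09 ± 0.49 with edgeR, DESeq2 adjusted p 0.0145). This row stood at 9.42 ± 5.01 CPM in DMSO and 19.7 ± 0.85 with olaparib. The interaction had a log2 value of -0.18 ± 0.79 for Usp18, and the interferon list read through the opposite strand had an adjusted p of 0.758. The edgeR count was 1 without olaparib replicate 1 (mt-Tq, 0.0466), without EZM8266 replicate 2 (Gm27177, 0.0446) and with the filter of 1 CPM (Gm27177, 0.0142). That filter also moved 2 lists past the threshold in this reading, H3K9 methylation and fatty acids, both lower (0.0421 each). The median SE of the interaction was 0.56, which limits what could be detected.

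The changes with EZM8266 against DMSO and with the combination against olaparib share no library, and were compared across rows, which are not independent replicates. Both comparisons set libraries with sample numbers from 33 to 36 against libraries with numbers from 41 to 44. An effect of that block would therefore give the same rows and signs in both. All 13 rows called in the first had the same sign in the second, and all 6 rows called in the second had the same sign in the first. Both called Serpinb9b, F13a1, Thbs1, Trdc and Gdnf, 5 rows where 0.012 would be shared if each row were equally likely to be called. That does not hold here, since both comparisons come from 1 fit with the same row spreads. Over 6379 rows Pearson's r was 0.289 and Spearman's rho 0.204, and over the 1329 rows with a mean of at least 100 counts r was 0.668 and rho 0.363. Part of this came from satellite-like rows such as Gm10800. Without the 13 of them r was 0.252, and 0.448 over 1323 abundant rows. Leaving out 1 library lowered r over all rows to 0.149 without DMSO replicate 1, 0.165 without olaparib replicate 1, 0.178 without EZM8266 replicate 1 and 0.133 without combination replicate 2. The changes with olaparib against DMSO and with the combination against EZM8266 had an r of 0.011 and a rho of -0.015, and an r of -0.032 over abundant rows.

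**Figure D4:**
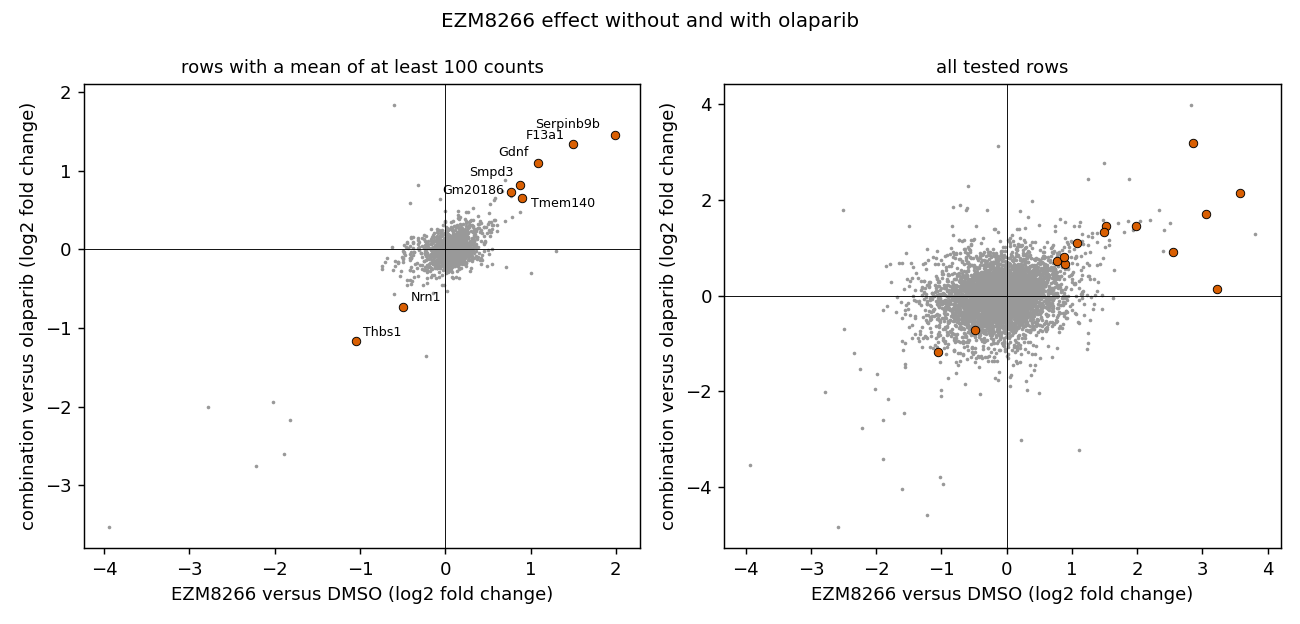
The log2 fold change of the combination against olaparib is plotted against that of EZM8266 against DMSO, with 1 point per row, for rows with a mean of at least 100 counts on the left and all 6379 tested rows on the right. Coloured points are rows called in either comparison, and all of them have the same sign on both axes.

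On the rows of the members, 24 of the 30 lists had at least 5 tested rows, and the tests that did not pass had camera adjusted p values from 0.0648 to 0.998 over the 6 comparisons. These rows count fragments on the strand opposite to the members' transcripts, so tests that did not pass do not decide on expression of these lists. Besides those named above the lists covered H3K9 methylation, PARP enzymes, imprinted genes, nucleic acid sensing, MHC class I, chemokines, p53 targets, homologous recombination, end joining, DNA replication, mitosis, cholesterol, fatty acids, the integrated stress and unfolded protein responses, autophagy, hypoxia, NRF2 targets, mesothelial markers, mitochondrial genes and nuclear noncoding RNAs. In the reading through the opposite strand 17 lists were tested, and the tests that did not pass had adjusted p values from 0.0605 to 0.987. Some of these lists passed without 1 library, for example fatty acids on the rows of the members, lower with EZM8266 against DMSO without DMSO replicate 1 (0.039) or EZM8266 replicate 1 (0.0191). In the reading through the opposite strand Adar, the RNA-editing enzyme of the nucleic acid sensing list (Chrnb2 row), had a log2 fold change of 0.62 ± 0.14 with the combination against DMSO (p 0.00384 adjusted over the list alone). Germline genes had 1 tested row of 43 members, immune cell markers 1 of 23, endothelial and stromal markers 0 of 19, drug efflux transporters 3 of 17, aryl hydrocarbon receptor targets 3 of 13 and Wnt targets 4 of 25, too few to test, so markers of other cell types could not be assessed as lists.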

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

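The settings without DMSO replicate 1 and olaparib replicate 2 together, by class of row, with the leakage covariate, with crossed numbers and with satellite-like rows removed, the reading of lists through the opposite strand and all averaged comparisons were chosen after seeing the data. Counts of called rows are given below in the order olaparib (0), EZM8266 (13) and the combination (14) against DMSO, the combination against olaparib (6) and against EZM8266 (0), and the interaction (0). They were 0, 15, 16, 8, 1 and 1 with DESeq2, 0, 13, 14, 5, 0 and 0 with RLE scaling, 8, 42, 45, 42, 12 and 7 with no filter on low counts, and 0, 19, 20, 7, 1 and 1 with the filter of 1 CPM in 4 libraries, which was meant as stricter but kept 14446 rows. With only the 2 groups compared they were 0, 3, 21, 11 and 0, and the interaction has no such fit. Without DMSO replicate 1 and olaparib replicate 2 together they were 1, 3, 5, 5, 0 and 0. Exon-class rows alone gave 0, 23, 27, 18, 1 and 0, and counts summed per opposite-strand gene 0, 26, 26, 17, 1 and 0. With the leakage share as a covariate they were 0, 46, 59, 40, 1 and 1, and without the 6 most abundant rows 0, 13, 14, 6, 0 and 0. With each library left out in turn they ranged from 0 to 1, 5 to 24, 6 to 19, 4 to 13, 0 to 3 and 0 to 1. Fewer libraries in a fit, or a changed number of tested rows, are part of these settings. Fits with 1 library left out tested more rows (7133 to 7660) than the main fit (6379), and exon-class rows alone were fewer (3555). The cause of the other moves was not tested.

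Libraries with the same replicate number deviated from their group means together in the olaparib, EZM8266 and combination groups (correlations of 0.22 to 0.29), and DMSO ran the opposite way (-0.31, -0.32 and -0.15), so the numbers did not pair all 4 groups. A replicate block gave 0, 10, 15, 5, 0 and 0 called rows, 51 for EZM8266 averaged over olaparib, 0 for olaparib averaged over EZM8266, correlations of 0.286 and -0.006, and 4 and 9 lists in the readings of the members' rows and of the opposite strand. A block with the DMSO numbers crossed gave 1, 84, 73, 47, 3 and 3 called rows, and 133 and 0 for EZM8266 and olaparib averaged.

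Over the 33 called results of named rows, 396 values with DESeq2, RLE scaling, the replicate block, 1 library left out or, added after seeing the data, only the 2 groups compared held 299 in the same direction past the threshold, 97 in the same direction and not past it, and 0 reversed. Serpinb9b and F13a1 in 3 comparisons each, Thbs1 and Gdnf in the comparisons of the combination with DMSO and with olaparib, and Entpd4b with EZM8266 against DMSO, 11 results, passed in each of these. The uncalled Parp1 row had a log2 fold change of -0.34 with olaparib, -0.64 to 0.15 with 1 library left out, highest without DMSO replicate 2, and the uncalled Ehmt2 row -0.36 with the combination against DMSO, -0.96 to 0.082 with 1 library left out, highest without combination replicate 2. The cause of these changes of sign was not tested. EZM8266 averaged over olaparib called 48 rows, 96 with no filter, 30 without DMSO replicate 1 and olaparib replicate 2 together, and 40 to 58 with 1 library left out. Olaparib averaged over EZM8266 called 0 with edgeR (115 unadjusted) and 0 with DESeq2, and 15 with no filter. The correlation of EZM8266 effects (0.289) was 0.056 with no filter, 0.107 with the filter of 1 CPM, 0.133 to 0.226 with 1 library left out, 0.252 without satellite-like rows, 0.668 over rows with a mean of at least 100 counts and 0.448 over these without satellite-like rows. The correlation of olaparib effects (0.011) was -0.136 to 0.095 with 1 library left out, -0.032 over abundant rows and -0.099 over these without satellite-like rows. With an estimated correlation 0 lists passed in either reading, against 3 and 9 with the preset one, with the filter of 1 CPM 3 and 7 passed, not all of them the same lists, and with 1 library left out 1 to 15 and 3 to 8 passed. The thin coverage, with a median SE of 0.38 to 0.41 per row in the comparisons of 2 groups, limits every count.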

Other observations

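The comparisons that average EZM8266 over libraries with and without olaparib, and the test of leakage against rows without annotation on the other strand, were chosen after the results were seen. Averaged in this way, 4 libraries with EZM8266 against 4 without it, 48 rows passed the edgeR threshold, 42 higher and 6 lower, 35 of them over an opposite-strand exon and 17 also called in a comparison of 2 groups. Without DMSO replicate 2 the balance was 37 higher and 16 lower, with no filter on low counts 69 and 27, and with the crossed block described below 93 and 40. Among the rows not called in a comparison of 2 groups, fragments rose on the strands of Lsr, a tight junction protein (Gm4673 row, 249 ± 23.2 to 406 ± 30.8 CPM, SD, n = 4; log2 fold change 0.62 ± 0.09, SE), the linker histone H1f0 (Gm49544 row, 0.72 ± 0.11), Heg1 (Gm15657 row, 0.55 ± 0.09), the selenium carrier Selenop (Ccdc152 row, 0.70 ± 0.12), the metalloproteinase Mmp24 (BC029722 row, 1.85 ± 0.30) and the basement membrane protein Nid1 (Gm48682 row, 1.15 ± 0.23). Lower levels were found on the strands of the adhesion molecule Ncam1 (Gm11149 row, -0.42 ± 0.07), the sodium pump subunit Atp1b1 (Nme7 row, -0.42 ± 0.09) and the collagen-modifying enzyme P3h2 (Gm4524 row, -0.39 ± 0.08). The row of the neurotrophin gene Bdnf, which overlaps the noncoding Gm45346, rose from 5.89 ± 2.15 to 19.5 ± 5.46 CPM (1.63 ± 0.32). These genes were chosen after their values were seen.

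Chance was not excluded for this count by a test that treats the 8 libraries as exchangeable. Of the 35 splits of the 8 libraries into 4 and 4, 2 gave at least 48 rows, and the highest other gave 160. That split sets DMSO replicate 1, olaparib replicate 2, EZM8266 replicate 2 and combination replicate 2 against the rest, with 1 library of each group on each side. It follows the replicate numbers with those of DMSO crossed, and points to a structure of the samples that the groups do not follow and the test does not allow for. With that split as a block, chosen from the same data, EZM8266 averaged over olaparib called 133 rows, among them all 48, and with the replicate numbers as labelled in a block 51. The 4 libraries on its first side have the lowest leakage shares, 1.04% to 1.42%. They also hold less of their counts in the 6 most abundant rows, 25.9% to 30.2% against 32.1% to 42.5% in the rest. Rows on the strands of Gm42418 and Rmrp are among these. Their share in the gene body class is higher, 5.9% in each against 4.7% to 5.2%. Which of these measures, if any, underlies the split was not tested. The remaining splits gave at most 1 row. Olaparib averaged over EZM8266 called 0 rows with edgeR (115 unadjusted) and 0 with DESeq2. Any split gives at least 0 rows, so all 35 gave as many whatever the data, and the test could not decide for olaparib.

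The rows called with EZM8266 against DMSO were set against technical explanations. With the leakage share as a covariate their median signed log2 fold change was 101.8% of its value and all 13 passed. Leakage differed widely within groups (1.24% and 1.68% in DMSO, 1.55% and 1.04% with EZM8266). A row that follows leakage would thus hardly be called, so this test could not decide on leakage. Without DMSO replicate 1 and olaparib replicate 2 the median was 97.7% of its value (1.49 against 1.53), with 13 of 13 in the same direction. Rows were called where the libraries of a group lay close together, so omitting a library could hardly move this median. The test therefore could not decide on genomic DNA in DMSO replicate 1. For the 12 rises, counts added to these same rows in a DMSO library would shrink the change and not make it. Counts added to other rows enter the library total, and their effect on the rises was not tested. A batch following the sample numbers cannot be told apart from EZM8266, since 0 libraries have a number in the block of the other kind. An effect of EZM8266 therefore stays a hypothesis beside that batch.

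The satellite-like rows that are high in DMSO replicate 1 and olaparib replicate 2 may come from genomic DNA. Over 1493 rows of olfactory and vomeronasal receptors with no annotation on the other strand, the lower of these libraries had 143 CPM and the highest of the other 6 had 129, a ratio of 1.11 (95% interval 0.87 to 1.41), which does not decide it. An exchange of labels between the DMSO and olaparib groups was tested by the correlation with the combination against EZM8266, -0.11 as labelled and -0.048 crossed over 1207 rows, a difference in size of -0.062 with a bootstrap SD of 0.0722, which does not decide it either. By correlation of log2 CPM across the tested rows, DMSO replicate 1 is nearest to olaparib replicate 2 (0.967) and DMSO replicate 2 to olaparib replicate 1 (0.974), as an exchange needs, but all 8 libraries are nearest to a library of another group, so this does not single it out. The 0 calls for olaparib against DMSO are open to this doubt. So are the interferon list with olaparib, the other comparisons that have either group as control, and the interaction. No biological explanation was tested, since each library has a partner in its own group without the pattern.

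Rows with no annotation on the other strand rose and fell together between libraries, with medians from 10.3 to 17.3 CPM. A candidate explanation is leakage of each row's own transcript. The leakage share correlated with these medians over the 8 libraries at Pearson's r 0.828 (exact permutation p 0.0145) and Spearman's rho 0.667 (exact permutation p 0.0831), both two-sided. Without EZM8266 replicate 2 and DMSO replicate 2, the farthest in leakage, r was 0.479, so the relation rests on those libraries. This was the 1 relation computed across libraries.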
